A study of Homo sapiens with 41 samples.

How the data were processed

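RNA sequencing libraries of human blood were analysed from the deposited gene tables alone; no sequence reads were used. Per the labels, 41 libraries came from 21 persons, of whom 11 were patients with VEXAS syndrome and 10 were healthy controls. VEXAS syndrome is an adult-onset inflammatory disease that arises from somatic mutations of UBA1, the main E1 enzyme that activates ubiquitin, in blood-forming cells. Per the labels, whole blood was drawn into tubes that preserve RNA. Mononuclear cells were separated on a density gradient, and monocytes were pulled out with magnetic beads that carried antibodies to CD14. The cells left behind form the CD14-depleted fraction, and neutrophils were taken from the red cell pellet after dextran sedimentation and lysis of red cells. The libraries were made with a stranded kit for polyadenylated RNA. The labels gave no treatment, sampling date or sequencing batch.

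The deposited count files held raw counts of fragments per gene, whole numbers that the authors had not normalised. Per the file headers, fragments were counted over the exons of each gene name on GRCh37 with featureCounts, version 1.6.3 for whole blood and version 2.0.0 for the cell fractions. No strand option and no option for fragments with several positions were set. Genes that overlap on opposite strands, and paralogs of nearly the same sequence, are therefore uncertain. The alignment names in the headers marked the removal of haemoglobin reads before whole blood was counted, and a STAR 2.5.3a alignment for the fractions. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic and aligned with STAR 2.5.3a, and bedtools, Subread and DESeq2 were also used. The authors also deposited 4 tables, each comparing patients with controls in whole blood or in a fraction. These deposited tables held a log2 fold change, a p-value with an adjusted p-value, and group means as a score, namely the mean of counts divided by size factors and rounded to whole numbers. The 82 columns of these tables that hold single libraries were not used, since the count files give the same libraries as raw counts.

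Each count file listed 34225 genes. The 226 genes on chromosome Y or named XIST or TSIX were left out of every step, so that no value could tell a person's sex; they held at most 0.174% of a library's counts. The other 33999 genes were kept. The unit of replication was the person. For 2 patients the labels name 2 whole blood libraries, A and B, and their counts were summed, which left 6 controls and 11 patients for whole blood. The CD14+ monocytes and the CD14-depleted cells came from 3 controls and 4 patients each, and the neutrophils from 4 controls and 4 patients. In 2 of the 19 whole blood libraries the sample name in the file header named the other group. The labelled groups were kept, because the group means in the authors' deposited whole blood table equalled the means over the labelled groups for 100% of the 15035 genes with a mean of at least 10, within 1 count plus 1%. With the groups that the headers name, 19.7% of these genes matched.

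Patients and controls were compared within whole blood and within each fraction with the edgeR quasi-likelihood test (R 4.3.3, edgeR 4.0.16, limma 3.58.1), with filterByExpr as the filter on low counts, TMM normalisation and disease as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are patients over controls, on the log2 scale with the standard error of the fit, and levels are CPM, counts scaled by the normalised library size, with the SD over persons. Whether the patient effect differed between fractions was tested in 1 fit of the 22 fraction libraries with 6 group means, as the difference of the log2 fold changes. Genes changed in the same direction in a pair of fractions were counted, and all 35 relabellings of the persons served as the comparison.

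The 33 gene lists and the rule for naming genes were set before the data were examined, as were the alternatives other than those given as chosen after seeing the data. Each list was tested with camera (limma) at a preset correlation between genes of 0.01, and again with the estimated correlation and with fry, adjusted over the 33 lists of a comparison. Members past the threshold were counted over all genes tested and also adjusted over the list alone. The genes named are UBA1, the 6 genes per direction with the smallest p, and up to 4 members per list with the smallest p. The genes with the smallest p also had a log2 fold change of at least 1 in size and a mean of at least 8 CPM in the higher group, with no overlap between the groups (in whole blood, at most 1 person inside the other group's range). For differences between fractions, 4 genes per direction were named without the overlap condition. Immunoglobulin and T cell receptor segments and genes with clone-based names were not named.

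The comparisons were tested on simulated data with the same sizes and spreads. In each, 100 genes were changed 2-fold and 100 were changed 4-fold before the filter on low counts. The adjusted threshold is less strict where more genes change, as in the real neutrophils with 2144 genes called. The shares recovered below therefore need not hold for the real comparisons. With edgeR, 4-fold changes were recovered for 87.6% of changed genes in whole blood, 85.9% in CD14+ monocytes, 64.2% in neutrophils and 57.7% in CD14-depleted cells. For 2-fold changes the shares were 24%, 40.8%, 4.3% and 4.2%. False calls were 8 of 116, 9 of 128, 5 of 70 and 4 of 64 with edgeR. With DESeq2 1.42.0 they were 33 of 167, 48 of 197, 30 of 126 and 71 of 181. For differences between fractions, 4-fold differences were recovered for 47.5% (CD14+ monocytes against neutrophils), 47% (CD14+ monocytes against CD14-depleted cells) and 48% (neutrophils against CD14-depleted cells) of changed genes. In the same order, 2-fold differences were recovered for 10.2%, 2.1% and 6.2%, and false calls were 3 of 60, 7 of 56 and 2 of 55. In simulated neutrophils 0 of 33 unchanged lists were called, and a list of 20 raised genes was called with a camera adjusted p of 2.08e-20. The simulated genes varied independently of each other, so this cannot tell how often camera calls unchanged lists whose genes move together. In the real whole blood the estimated correlation was 0.752 for the interferon-stimulated genes.

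Whether libraries belong together was checked on the log2 CPM after removal of group means. Fractions of the same person correlated across genes, with a Pearson r of 0.27 to 0.40 for CD14+ monocytes and neutrophils (7 pairs). The range was 0.29 to 0.41 for CD14+ monocytes and CD14-depleted cells (6 pairs) and 0.09 to 0.40 for neutrophils and CD14-depleted cells (7 pairs). In every one of these pairs the library correlated best with that of its own person among the persons of the same disease group. Few persons were compared in this way, and removal of group means tends to lower correlations between different persons of a group. A fit with the person as a block was also run for the differences. No pair of libraries was identical. Without removal of group means, the A and B whole blood libraries of the 2 patients correlated at an r of 0.909 and 0.994. Pairs of different patients in whole blood had a median r of 0.916. The labels do not say whether A and B are repeats or separate draws.

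The alternatives were size factors of the DESeq2 kind (RLE), no filter on low counts, the DESeq2 Wald test, removal of haemoglobin genes, leaving out each person, a joint fit of the fractions, other uses of the A and B libraries, blocks, fewer patients, and list means as covariates. DESeq2 also used its own size factors and filter, and the joint fit tested more genes. Other splits of the persons into groups of the same sizes were run as well: all 35 where there were that many, and 100 drawn with a fixed seed for whole blood.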

Results

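The data describe gene expression in blood of patients with VEXAS syndrome and of healthy controls. Whole blood was measured in 6 controls and 11 patients. CD14+ monocytes and CD14-depleted mononuclear cells, the remainder from which monocytes were removed, were each measured in 3 controls and 4 patients, and neutrophils in 4 controls and 4 patients. The 4 patients who gave fractions also gave whole blood. Total counts per library ranged from 8929279 to 28100984 in control whole blood and from 1162987 to 33199665 in patient whole blood. They ranged from 20394237 to 24770724 in control and from 21624296 to 24002221 in patient CD14+ monocytes, and from 18739992 to 20462758 in control and from 17228896 to 19585068 in patient neutrophils. In CD14-depleted cells the range was 18036375 to 19400018 in controls and 12114666 to 21291334 in patients. The libraries carried no molecular identifiers that the labels mention, so depth speaks for counting error only, and the precision of each fold change is given by its standard error over persons.

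**Figure D1:**
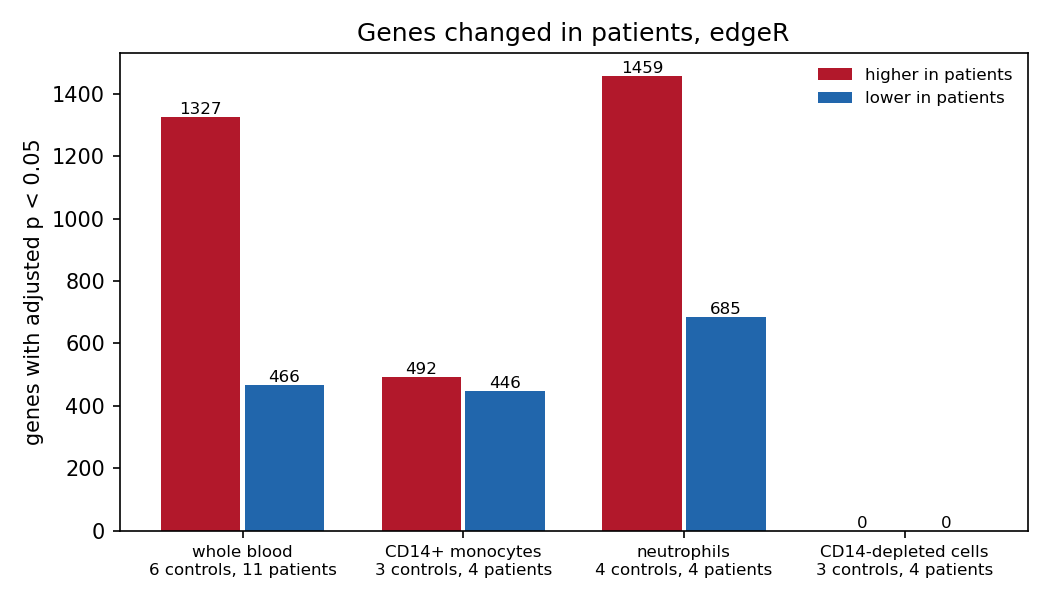
Number of genes past an adjusted p of 0.05 in edgeR, higher (red) or lower (blue) in patients than in controls, for whole blood and for each cell fraction. The bars stand at 1327 and 466 genes in whole blood, 492 and 446 in CD14+ monocytes, 1459 and 685 in neutrophils, and 0 in CD14-depleted cells.

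The whole blood comparison asks which genes differ between patients and controls in the circulating cells as a whole. CSF1R, the receptor for the monocyte growth factor CSF1 (chromosome 5, 149432854 to 149492935), fell to 0.189 of the control level, from 232 ± 67.2 CPM (SD, n = 6) to 44.0 ± 21.5 CPM (SD, n = 11), with a log2 fold change of -2.40 ± 0.29 SE (adjusted p = 0.00021). The 11 patients lay below all 6 controls for CSF1R, where the rule for naming allowed at most 1 person inside the other group's range. HORMAD1, a protein of meiotic chromosomes (chromosome 1, 150670535 to 150693364), rose 13.9-fold (log2 3.79 ± 0.48).

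Other genes with small p that rose were CA12, a membrane carbonic anhydrase, ANKRD22, CHPT1, an enzyme of phosphatidylcholine synthesis, and ABCC13, with log2 fold changes of 4.68, 5.04, 2.97 and 5.27. Those that fell were TPPP3 (log2 -3.70), CDKN1C, an inhibitor of cyclin-dependent kinases (log2 -3.93), FCER2, the B cell receptor for IgE (log2 -3.42), MS4A7 (log2 -2.14) and CD180 (log2 -1.36). UBA1 (chromosome X, 47050199 to 47074527) was at 235 ± 35.2 CPM in controls and 255 ± 112 CPM in patients. Its log2 fold change of 0.12 ± 0.26 did not pass the test (adjusted p = 0.79). Of the 103 named genes past the threshold in whole blood, 76 stayed past it whichever person was left out.

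Of the 24 immature neutrophil granule genes, all 24 rose, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 4.75. Examples are ARG1 (4.46 ± 0.69), the defensin DEFA4 (4.91 ± 0.80), CEACAM8 (5.03 ± 0.83), whose paralog CEACAM6 makes its count uncertain, and the collagenase MMP8 (6.60 ± 1.14). Camera gave the list an adjusted p of 5.94e-22, and adjusted p = 0.183 with an estimated correlation. Of 17 erythroid genes, 16 rose (17 adjusted over the list alone), with a median of 3.39. CA1, red cell carbonic anhydrase, rose by 6.69 ± 1.01 and HEMGN by 3.71 ± 0.53. The erythroid list had a camera adjusted p of 6.51e-22, and adjusted p = 0.117 with an estimated correlation. The stem and progenitor genes ERG (4.34 ± 0.66) and TAL1 (2.24 ± 0.39) rose, and the other 6 members tested did not pass. Of 23 proliferation genes, 9 rose (18 adjusted over the list alone), CCNB2, CDK1 and MKI67 among them. Their median was 1.46, with a camera adjusted p of 3.82e-06 and adjusted p = 0.5 with an estimated correlation.

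Of 18 B cell genes, 15 fell (17 adjusted over the list alone), with a median log2 fold change of -2.11. TCL1A fell by 4.75 ± 0.85, CR2 by 2.49 ± 0.46 and CD79B by 2.03 ± 0.39. Camera gave an adjusted p of 1.2e-19, and adjusted p = 0.154 with an estimated correlation. Of 13 dendritic cell genes, 7 fell, with CD1C at -2.76 ± 0.40, TCF4 at -1.44 ± 0.21 and LILRA4 at -2.44 ± 0.48. That list had a camera adjusted p of 9.68e-06 and adjusted p = 0.0526 with an estimated correlation. Of 24 T cell genes, 0 passed the test in edgeR and 0 in DESeq2, 2 had an unadjusted p under 0.05, and the list median was -0.43 (camera adjusted p = 0.00237, adjusted p = 0.634 with an estimated correlation).

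Of 30 interferon-stimulated genes tested in whole blood, 7 rose (24 adjusted over the list alone), with OASL at 2.0 ± 0.44, IFI27 at 5.89 ± 1.44 and the RNA sensor IFIH1 at 1.39 ± 0.35. IFI27 stood at -0.54 with the T cell and erythroid list means as covariates and at -0.27 with the groups in the file headers. The list median was 1.41, with a camera adjusted p of 6.46e-09 and adjusted p = 0.5 with an estimated correlation. Of 29 interferon-gamma and antigen processing genes, 11 rose and 2 fell (16 and 2 adjusted over the list alone), with GBP1 at 2.64 ± 0.53 and CD274, which encodes PD-L1, at 2.65 ± 0.54. FCGR1A (3.02 ± 0.53) rose too, but it shares sequence with FCGR1B. That list had a camera adjusted p of 4.8e-05, and adjusted p = 0.5 with an estimated correlation. Among TNF and NF-kB targets, 6 of 31 rose and 0 fell (7 rose adjusted over the list alone), TNFAIP6 by 3.50 ± 0.58 and ICAM1 by 1.23 ± 0.27. Of 22 inflammasome and IL-1 family genes, 7 rose (12 rose and 1 fell adjusted over the list alone), with the DNA sensor AIM2 at 2.58 ± 0.48 and the receptor IL1R1 at 2.54 ± 0.63. Camera adjusted p values for these lists were 0.0004 and 0.0017, and adjusted p = 0.5 with an estimated correlation for each.

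Of 18 integrated stress response genes tested in whole blood, 6 rose (10 adjusted over the list alone), among them the amino acid transporters SLC7A11 (3.26 ± 0.56) and SLC7A5 (2.01 ± 0.35) and the growth arrest gene GADD45A (2.75 ± 0.50). That list had a camera adjusted p of 4.8e-05, and adjusted p = 0.117 with an estimated correlation. Of 26 unfolded protein response genes, 0 rose and 1 fell, SYVN1 at -0.55 ± 0.17. Leaving out any of 10 persons ended the SYVN1 call, and its highest adjusted p was 0.11. Of 35 genes for ubiquitin and E2 enzymes, 8 rose and 1 fell (15 and 2 adjusted over the list alone), with CDC34 at 1.76 ± 0.34, the ubiquitin gene UBB at 2.19 ± 0.54 and UBE2E2 at -2.01 ± 0.39. With the T cell and erythroid list means as covariates, CDC34 stood at -0.10 and UBB at -1.14. Their camera adjusted p was 0.000347, and adjusted p = 0.5 with an estimated correlation. Of 20 glucocorticoid response genes, 8 rose (14 adjusted over the list alone), with MAOA at 7.0 ± 1.21 and FKBP5 at 2.81 ± 0.62. Camera gave them an adjusted p of 4.8e-05, and adjusted p = 0.5 with an estimated correlation.

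In edgeR, 1793 of the 15427 genes tested changed in whole blood: 1327 rose and 466 fell. Camera called 20 of the 33 lists, 16 up and 4 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.0526. The authors' deposited table, which came from DESeq2, called 2950 genes, and 1764 of the 1793 genes were also called there in the same direction. Own DESeq2 fits called 3227. The count was 1186, 1115, 1101 and 1149 without control 3, 4, 5 and 6 respectively, and 1135 with the 4 patients who gave fractions as the only patients. It was 78 with the means of the T cell and erythroid lists as covariates, 1044 without the 2 libraries whose headers name the other group, and 0 with their groups taken from the headers.

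The comparison of CD14+ monocytes asks what differs in the CD14+ fraction. TRIM25, a ubiquitin ligase of the antiviral RIG-I pathway (chromosome 17, 54965270 to 54991409), rose 2.61-fold, from 234 ± 22 CPM (SD, n = 3) to 612 ± 22.3 CPM (SD, n = 4), with a log2 fold change of 1.39 ± 0.10 SE (adjusted p = 0.0028). PTMS, which encodes parathymosin (chromosome 12, 6875483 to 6880118), rose 4.15-fold, from 15.3 ± 1.31 CPM to 63.7 ± 8.61 CPM (log2 2.05 ± 0.15). SNED1 (chromosome 2, 241938255 to 242033643) fell from 24.8 ± 2.14 CPM to 6.10 ± 0.778 CPM (log2 -2.03 ± 0.15). The membrane protein genes MS4A14 and MS4A7, neighbours on chromosome 11, fell by 1.95 ± 0.17 and 1.6 ± 0.15 on the log2 scale. For each of these genes the patients did not overlap the controls, which was a condition for naming them and adds no support.

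The other genes with the smallest p that rose were NPL, an enzyme that breaks down sialic acid (1.23), SIPA1L2 (1.69), DNASE2, the lysosomal DNase (1.39), and SRXN1, which repairs oxidised peroxiredoxins (1.31). The others that fell were ZCCHC14 (-1.17), PRKACB, a catalytic subunit of protein kinase A (-1.44), and GPR155 (-1.63). UBA1 was at 173 ± 5.59 CPM in controls and 167 ± 5.32 CPM in patients, a log2 fold change of -0.06 ± 0.08 that did not pass (adjusted p = 0.7). Of the 68 named genes past the threshold in CD14+ monocytes, 22 stayed past it whichever person was left out.

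Of 22 IL-6 and STAT3 pathway genes tested in CD14+ monocytes, 5 rose (8 adjusted over the list alone), with the feedback inhibitor SOCS3 at 2.17 ± 0.28, from 336 ± 59.6 CPM to 1510 ± 536 CPM. The list had a camera adjusted p of 6.77e-06, and adjusted p = 0.291 with an estimated correlation. Of 23 inflammasome and IL-1 family genes, 3 rose (5 rose and 1 fell adjusted over the list alone), with IL1R1 at 2.95 ± 0.28. By camera the adjusted p was 0.00252, and adjusted p = 0.291 with an estimated correlation. Of 30 interferon-stimulated genes, 3 rose (11 adjusted over the list alone): IFIH1 at 0.76 ± 0.14, EIF2AK2 at 1.12 ± 0.22 and OASL at 1.6 ± 0.36, each of which lost its call on leaving out some persons (highest adjusted p 0.1 for IFIH1, 0.11 for EIF2AK2 and 0.14 for OASL). Their median was 0.97, with a camera adjusted p of 4.92e-10 and adjusted p = 0.431 with an estimated correlation.

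Of 22 autophagy and lysosome genes, 5 rose (6 adjusted over the list alone), with cathepsin D (CTSD) at 1.10 ± 0.11 and the autophagosome gene MAP1LC3B at 1.06 ± 0.13. That list had the lowest p with an estimated correlation among the lists of CD14+ monocytes (camera adjusted p = 7.93e-06, adjusted p = 0.131 with an estimated correlation). Of 25 glycolysis and hypoxia genes, 4 rose and 0 fell (7 and 2 adjusted over the list alone), with adrenomedullin (ADM) at 1.72 ± 0.19. Their camera adjusted p was 0.0037, and adjusted p = 0.291 with an estimated correlation. MDM2, the ligase that degrades p53, rose by 1.11 ± 0.14, alone among 18 p53 targets (2 adjusted over the list alone).

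Of 14 CD16 monocyte genes tested in CD14+ monocytes, 3 fell, both over all genes and adjusted over the list alone, with the chemokine receptor CX3CR1 at -1.28 ± 0.17 and CDKN1C at -2.46 ± 0.36. Camera gave them an adjusted p of 0.00252, and adjusted p = 0.548 with an estimated correlation. Of 20 monocyte genes, 5 rose and 2 fell (9 and 2 adjusted over the list alone), the latter MS4A7 and CSF1R. The list had a camera adjusted p of 0.00671, and adjusted p = 0.323 with an estimated correlation. Of 11 dendritic cell genes, 3 fell (4 adjusted over the list alone), with CD1C at -1.94 ± 0.26. Of 12 B cell genes, 3 fell (6 adjusted over the list alone), from a low level: CD79B went from 17.5 ± 6.57 CPM to 5.66 ± 1.72 CPM, with a highest adjusted p of 0.081 on leaving out 1 person. These lists had camera adjusted p values of 0.00252 and 1.77e-05, and adjusted p = 0.291 and adjusted p = 0.323 with an estimated correlation. Of 20 mature neutrophil genes, 4 rose, with the gelatinase MMP9 at 3.13 ± 0.36 (camera adjusted p = 4.26e-05, adjusted p = 0.33 with an estimated correlation). Of 13 T cell genes, 1 fell, with a list median of -1.73 (camera adjusted p = 0.00663, adjusted p = 0.551 with an estimated correlation). That fall rests largely on 1 control, with a mean log2 CPM of the list of 2.88. The other controls stood at 0.74 and 0.79, and the patients at 0.36 to 1.02. Of 13 erythroid genes, 1 rose, with a median of 2.39 (camera adjusted p = 0.00943, adjusted p = 0.548 with an estimated correlation), and of 13 platelet genes, 2 rose (5 adjusted over the list alone; camera adjusted p = 0.00124, adjusted p = 0.291 with an estimated correlation).

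In edgeR, 938 of 14363 genes changed in CD14+ monocytes: 492 rose and 446 fell. Camera called 22 of the 33 lists, 16 up and 6 down, and 0 with an estimated correlation. Of the 938 genes, 936 changed in the same direction in the authors' deposited table, which called 2266; own DESeq2 fits called 2271. The count was 116, 154 and 144 without control 8, 9 and 10, and 432 and 458 without patient 10 and 11, and a joint fit of the 22 fraction libraries gave 266.

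The comparison of neutrophils asks the same of these cells. MOB3B (chromosome 9, 27325207 to 27529850) rose 12.5-fold, from 3.06 ± 0.295 CPM (SD, n = 4) to 38.1 ± 6.51 CPM (SD, n = 4), with a log2 fold change of 3.64 ± 0.22 SE (adjusted p = 0.00019). GGH, an enzyme that trims folate polyglutamates (chromosome 8, 63927638 to 63951610), rose 37.1-fold, from 0.668 ± 0.0348 CPM to 25 ± 9.40 CPM (log2 5.21 ± 0.35). HIST1H1C, a linker histone (chromosome 6, 26055968 to 26056699), fell from 62.3 ± 9.36 CPM to 15.4 ± 3.48 CPM (log2 -2.01 ± 0.22). In each case the 4 patients did not overlap the 4 controls, which was a condition for naming these genes and adds no support.

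Other genes with small p that rose were ZNF697 (4.53), PM20D2 (2.87), SLC26A8, an anion transporter (3.04), and PGAP1, an enzyme of GPI anchors (2.90). Those that fell were ITIH4 (-1.86), FBRSL1 (-1.24), NEURL4 (-1.46) and TMEM110 (-1.71). UBA1 was at 135 ± 30.7 CPM in controls and 203 ± 45.5 CPM in patients, a log2 fold change of 0.59 ± 0.23 that did not pass (adjusted p = 0.095). Of the 106 named genes past the threshold in neutrophils, 49 stayed past it whichever person was left out.

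In neutrophils, 11 of 25 glycolysis and hypoxia genes rose and 0 fell (16 and 1 adjusted over the list alone), with the glycolytic enzymes PKM at 2.20 ± 0.26, GAPDH at 1.46 ± 0.21 and ENO1 at 1.78 ± 0.26. By camera the adjusted p was 2.05e-05, and adjusted p = 0.54 with an estimated correlation. Of 41 oxidative phosphorylation genes, 1 rose and 3 fell, with the complex I subunit NDUFA10 at -0.94 ± 0.19. Of 21 autophagy and lysosome genes, 6 rose, over all genes and adjusted over the list alone, with the autophagy receptor SQSTM1 at 1.6 ± 0.26 and CTSD at 1.70 ± 0.29 (camera adjusted p = 0.000816, adjusted p = 0.54 with an estimated correlation). Of 33 genes for ubiquitin and E2 enzymes, 9 rose (13 rose and 2 fell adjusted over the list alone), with UBE2B at 1.12 ± 0.19. Their camera adjusted p was 0.00412, and adjusted p = 0.54 with an estimated correlation.

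Of 32 TNF and NF-kB targets tested in neutrophils, 9 rose (13 adjusted over the list alone), with the NF-kB subunit RELB at 2.12 ± 0.26, BIRC3 at 2.09 ± 0.35 and TNFAIP6 at 3.08 ± 0.52. Camera gave them an adjusted p of 2.71e-05, and adjusted p = 0.54 with an estimated correlation. Of 22 inflammasome and IL-1 family genes, 9 rose (11 rose and 1 fell adjusted over the list alone), with IL1R1 at 1.94 ± 0.34 and the inflammatory caspase CASP5 at 2.39 ± 0.45. The list had a camera adjusted p of 2.41e-05, and adjusted p = 0.54 with an estimated correlation. Of 28 interferon-gamma and antigen processing genes, 11 rose (15 adjusted over the list alone), with WARS at 1.82 ± 0.34. Of 29 interferon-stimulated genes, 5 rose, with IRF7 at 1.55 ± 0.31, a call that leaving out 1 of the persons ended (adjusted p 0.063). These lists shared a camera adjusted p of 9.29e-07, and had adjusted p = 0.54 and adjusted p = 0.586 with an estimated correlation. Of 22 IL-6 and STAT3 pathway genes, 6 rose (11 adjusted over the list alone), with the adaptor MYD88 at 1.63 ± 0.26 (camera adjusted p = 8.7e-05, adjusted p = 0.54 with an estimated correlation).

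In the stress pathways of neutrophils, 4 of 16 integrated stress response genes rose, with SLC7A11 at 3.23 ± 0.40 and SLC3A2 at 1.32 ± 0.24 (camera adjusted p = 0.00898, adjusted p = 0.54 with an estimated correlation). Of 26 unfolded protein response genes, 1 rose, the cochaperone DNAJC3 at 1.05 ± 0.19, and 3 fell, with DNAJB11 at -1.12 ± 0.21. MAOA rose by 6.26 ± 0.92 and the p53 target TP53I3 by 1.69 ± 0.29.

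Of 24 T cell genes tested in neutrophils, all 24 had a log2 fold change below 0 and 3 fell, over all genes and adjusted over the list alone, with a median of -1.18 (camera adjusted p = 1.02e-05, adjusted p = 0.586 with an estimated correlation). Of 59 cytosolic ribosomal protein genes, 0 passed in edgeR and 2 in DESeq2, 12 had an unadjusted p under 0.05, and the median was -0.66 (camera adjusted p = 2.59e-05, adjusted p = 0.716 with an estimated correlation). Of 20 mature neutrophil genes, 7 rose (10 adjusted over the list alone), with MMP9 at 2.16 ± 0.36 and S100A12 at 2.08 ± 0.38 (camera adjusted p = 7.14e-06, adjusted p = 0.54 with an estimated correlation). Of 24 immature neutrophil granule genes, 1 rose, ARG1 at 1.53 ± 0.35, which leaving out any of 5 persons brought below the threshold, and the median was 0.29. Of 10 CD16 monocyte genes, 4 rose (5 adjusted over the list alone), FCGR3A at 2.59 ± 0.49 among them, a count that is uncertain because FCGR3B shares its sequence (camera adjusted p = 0.00284, adjusted p = 0.54 with an estimated correlation).

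In edgeR, 2144 of 13762 genes changed in neutrophils: 1459 rose and 685 fell. Camera called 13 of the 33 lists, 11 up and 2 down, and 0 with an estimated correlation. Of the 2144 genes, 2136 changed in the same direction in the authors' deposited table, which called 3574; own DESeq2 fits called 3532. The count was 531, 1090 and 945 without control 8, 7 and 10, 725 and 1350 without patient 13 and 11, and 5152 without patient 1 (2395 rose and 2757 fell). It was 422 with the T cell list mean as a covariate, and 5360 in the joint fit of the fractions (2016 rose and 3344 fell).

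The comparison of CD14-depleted cells asks the same of the mononuclear cells left after monocytes were removed. In edgeR 0 of 16204 genes passed the threshold, with 2006 genes at an unadjusted p under 0.05; own DESeq2 fits called 750 genes, and the authors' deposited table called 738, of which 409 were higher and 329 lower. In the immature neutrophil granule list, ELANE, neutrophil elastase, was at 34.3 ± 13.3 CPM (SD, n = 3) in controls and 748 ± 558 CPM (SD, n = 4) in patients (log2 4.44 ± 0.63 SE, adjusted p = 0.12), and CTSG, cathepsin G, at 16.0 ± 3.27 and 269 ± 235 CPM (log2 4.07 ± 0.66). All 24 members of that list had a positive fold change, 24 passed adjusted over the list alone and 21 passed in DESeq2, with a median of 3.30 (camera adjusted p = 1.72e-37, adjusted p = 0.261 with an estimated correlation). UBA1 was at 143 ± 9.20 CPM in controls and 144 ± 18.1 CPM in patients, a log2 fold change of 0.01 ± 0.13 (adjusted p = 0.99).

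In edgeR, other lists in CD14-depleted cells had members past the threshold when adjusted over the list alone and 0 over all genes; over all genes DESeq2 called 16 proliferation, 10 B cell, 7 dendritic cell, 3 erythroid, 8 interferon-stimulated and 10 interferon-gamma and antigen processing genes. Adjusted over the list alone in edgeR there were 20 of 25 erythroid genes, higher in patients with a median of 4.28 (camera adjusted p = 1.23e-16, adjusted p = 0.385 with an estimated correlation). The size of that rise leans on single persons. The mean log2 CPM of the list was 0.81, 3.97 and 4.09 in controls and 5.54, 5.63, 6.19 and 9.12 in patients. Adjusted in the same way there were 19 of 23 proliferation genes, higher with a median of 1.6, among them TYMS at 2.28 ± 0.42 and BIRC5 at 2.11 ± 0.40 (camera adjusted p = 8.19e-24, adjusted p = 0.299 with an estimated correlation). B cell genes were lower, 18 of 18 with a median of -1.61 (camera adjusted p = 8.02e-23, adjusted p = 0.299 with an estimated correlation). Dendritic cell genes were lower for 7 of 13, with a median of -1.55 (camera adjusted p = 5.38e-11, adjusted p = 0.261 with an estimated correlation). Interferon-stimulated genes were higher for 6 of 30, with a median of 0.67, OASL at 1.23 ± 0.20 among them (camera adjusted p = 5.34e-11, adjusted p = 0.425 with an estimated correlation). Of 26 interferon-gamma and antigen processing genes, 7 were higher and 2 lower (camera adjusted p = 9.07e-05, adjusted p = 0.261 with an estimated correlation). Lower members numbered 4 of 10 HLA class II genes, 4 of 13 CD16 monocyte genes and 4 of 20 NK and cytotoxic cell genes (camera adjusted p = 0.00132, 4.57e-08 and 0.00204; adjusted p = 0.513, 0.299 and 0.521 with an estimated correlation). Of 20 monocyte genes, 1 was higher and 4 lower (camera adjusted p = 0.333). Of 24 T cell genes, 0 passed in edgeR, 6 had an unadjusted p under 0.05 and 1 passed in DESeq2; CD8A was at 238 ± 110 CPM in controls and 612 ± 261 CPM in patients (log2 1.36 ± 0.44, adjusted p = 0.28).

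Haemoglobin genes took 0.047 to 0.631% of the counts of control CD14-depleted cells and 0.575 to 2.036% of those of patients, and the 50 most abundant genes took 7.71 to 8.05% and 8.33 to 14.09%. Camera called 16 of the 33 lists in these cells, 11 up and 5 down, and 0 with an estimated correlation. Leaving out patient 11 gave 1 gene in edgeR and leaving out any other person gave 0, while the joint fit of the fractions, which shares the spread of all fractions, gave 389.

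**Figure D2:**
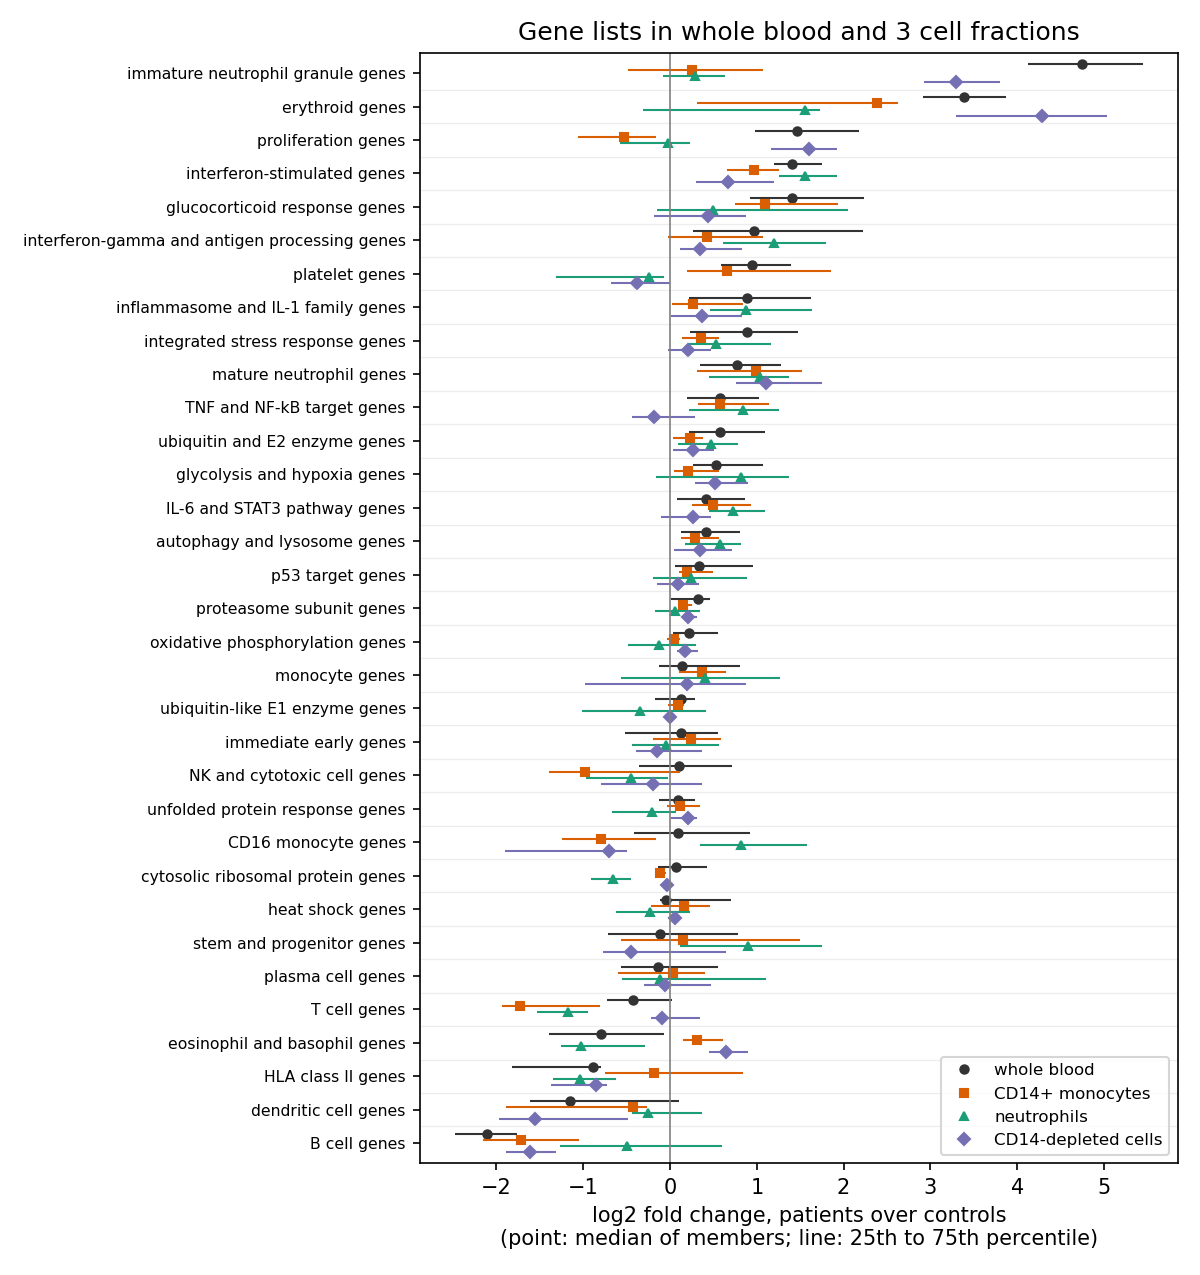
Median log2 fold change of patients over controls for the members of each of the 33 gene lists (points), with the range from the 25th to the 75th percentile of the members (lines), in whole blood and 3 cell fractions. Immature neutrophil granule genes stood at a median of 4.75 in whole blood and 3.30 in CD14-depleted cells, against 0.29 in neutrophils and 0.25 in CD14+ monocytes.

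Whether the patient effect differed between fractions was tested directly. Between CD14+ monocytes and neutrophils it differed for 668 of 17567 genes, with a higher fold change in CD14+ monocytes for 364 and in neutrophils for 304. RHOBTB3 had log2 fold changes of 3.12 in CD14+ monocytes and -0.96 in neutrophils (difference 4.08 ± 0.60 SE, adjusted p = 0.0014). The kinase scaffold KSR1 stood at 0.18 and -2.11, SLC47A1, an organic cation transporter, at 2.86 and -1.31, and the splicing factor RBM25 at 0.19 and -0.95. In the other direction, CEP97 stood at -0.48 in CD14+ monocytes and 1.78 in neutrophils (difference -2.26 ± 0.24, adjusted p = 0.000116), FRMD4B at -0.46 and 2.31, the nuclear import receptor TNPO1 at 0.26 and 1.83, and GPR155 at -1.64 and 0.78. Among the lists, 3 of 14 CD16 monocyte genes had a lower fold change in CD14+ monocytes (medians -0.81 and 0.25; camera adjusted p = 0.000163, adjusted p = 0.922 with an estimated correlation).

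The median difference of all genes between CD14+ monocytes and neutrophils was 0.141 with TMM and -0.016 with RLE scaling, and with RLE 229 genes had a higher fold change in CD14+ monocytes and 390 in neutrophils, of 619. With the person as a block the count was 969; it was 298 without a filter on low counts and 1584 with DESeq2. Leaving out 1 person gave 153, 382, 59 and 129 without control 10, 7, 8 and 9, and 325, 294, 169 and 3176 without patient 10, 11, 13 and 1. UBA1 did not pass (difference -0.52 ± 0.23, adjusted p = 0.199).

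Between CD14+ monocytes and CD14-depleted cells, 4 genes differed in edgeR. RHOBTB3 (3.12 in CD14+ monocytes and -1.46 in CD14-depleted cells, adjusted p = 0.00609), FAM20A, a pseudokinase of the secretory pathway (4.39 and -0.38, adjusted p = 0.0249), and DTX4, a ubiquitin ligase (1.24 and -1.55, adjusted p = 0.0249), had a higher fold change in CD14+ monocytes. FAM162A had a lower one (-2.04 and 0.15, adjusted p = 0.0249). No list had a member past the threshold; proliferation genes stood at medians of -0.40 and 1.55 (camera adjusted p = 4.17e-20, adjusted p = 0.0808 with an estimated correlation) and immature neutrophil granule genes at 0.53 and 3.27 (camera adjusted p = 1.16e-17, adjusted p = 0.301 with an estimated correlation). With the person as a block 20 genes differed, 3 of these 4 among them (DTX4 had an adjusted p of 0.0652), without a filter 9, and with DESeq2 163. Leaving out 1 person gave 0, 1, 0 and 0 without control 10, 7, 8 and 9, and 2, 0 and 28 without patient 11, 13 and 1. At an unadjusted p under 0.05 there were 1402 genes.

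Between neutrophils and CD14-depleted cells, 1011 of 17567 genes differed, with a higher fold change in neutrophils for 449 and in CD14-depleted cells for 562. MOB3B stood at 3.51 in neutrophils and -0.91 in CD14-depleted cells (difference 4.41 ± 0.43, adjusted p = 4.5e-05), TNPO1 at 1.83 and 0.03, PM20D2 at 2.74 and -0.02, and GALM, a sugar mutarotase, at 2.99 and 0.20. The replication helicase subunit MCM7 stood at -1.53 and 0.22 (difference -1.75 ± 0.29, adjusted p = 0.00329), NEURL4 at -1.58 and -0.27, ZNF3 at -1.56 and 0.02, and ICA1 at -1.78 and 1.98. Of 24 immature neutrophil granule genes, 7 had a higher fold change in CD14-depleted cells (medians 0.23 in neutrophils and 3.27; camera adjusted p = 2.4e-10, adjusted p = 0.565 with an estimated correlation). Of 14 CD16 monocyte genes, 6 had a higher one in neutrophils, and of 18 B cell genes, 4 did (camera adjusted p = 2.77e-07 and 1.66e-05, adjusted p = 0.565 with an estimated correlation for each). Of 23 proliferation genes, 4 had a higher one in CD14-depleted cells (camera adjusted p = 2.61e-06, adjusted p = 0.565 with an estimated correlation).

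The median difference of all genes between neutrophils and CD14-depleted cells was -0.217 with TMM and -0.065 with RLE scaling. With RLE, 549 genes had a higher fold change in neutrophils and 349 in CD14-depleted cells, of 898. With the person as a block the count was 1625; it was 484 without a filter and 2086 with DESeq2. Leaving out 1 person gave 516, 296, 108 and 139 without control 10, 7, 8 and 9, and 635, 426, 363 and 4128 without patient 10, 11, 13 and 1. UBA1 did not pass (difference 0.49 ± 0.23, adjusted p = 0.192).

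CD14+ monocytes and neutrophils shared 290 genes changed in the same direction, of 12728 tested in both. Of these, 213 rose and 77 fell, where independent changes would give 46.9 and 19.3, and 8 genes changed in opposite directions. Among the listed genes, the receptor TLR2, ITGAM, IL1R1, CTSD and MAP1LC3B rose and CSF1R fell in both. None of the other relabellings of the persons, out of 35, gave a shared gene. That 0 says little about sharing, since the other relabellings gave at most 2 changed genes in CD14+ monocytes and at most 39 in neutrophils. Fold changes correlated across genes with a Pearson r of 0.414, where the highest r of the other relabellings was 0.411; genes are not independent replicates. With CD14-depleted cells 0 genes were shared, since 0 passed there in edgeR. Fold changes in CD14-depleted cells correlated with those in CD14+ monocytes at r = 0.325 and with those in neutrophils at r = 0.316, and other relabellings reached 0.357 and 0.407.

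**Figure D3:**
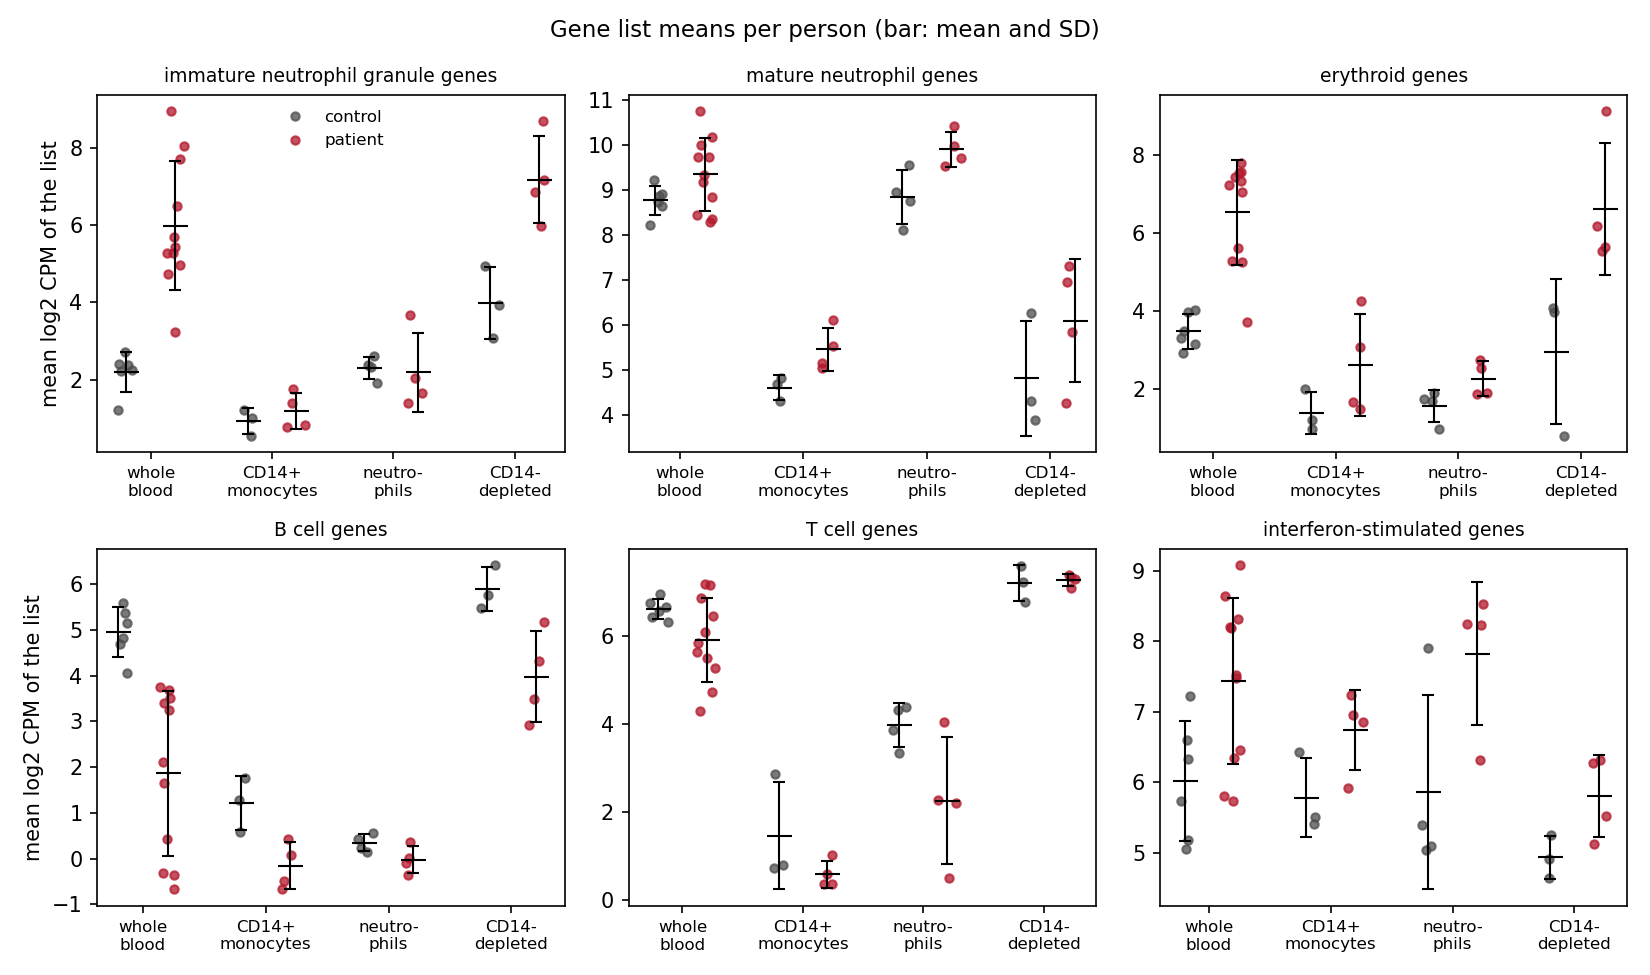
Mean log2 CPM of 6 gene lists in each person (points), with the mean and SD of each group (bars), for controls (grey) and patients (red) in whole blood and 3 cell fractions. The immature neutrophil granule list stood at 2.20 in controls and 5.98 in patients in whole blood, and at 3.99 and 7.17 in CD14-depleted cells.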

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

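The tests by other splits of the persons and those of mislabelling, depth, lymphocyte share, carry-over of neutrophil-fraction cells and lymphocyte carry-over were chosen only after the results were seen, and the test of 1 library that stands apart before.

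The patient effect differed between fractions for 668 genes (CD14+ monocytes against neutrophils), 4 genes (CD14+ monocytes against CD14-depleted cells) and 1011 genes (neutrophils against CD14-depleted cells), each by a test of the difference itself. For each of these 3 differences, 1 of the 35 splits of the persons, the real one, gave as many genes. This argues against chance without excluding it. The share of 0.029 is the smallest that 35 splits can give, and it was not adjusted over the comparisons. The highest other split gave 76, 0 and 12 genes. The 4 genes rest on few calls, with 0 to 28 genes on leaving out 1 person.

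Among 232 sets of values of 4 to 10 persons, 12 held a person far from the others, where chance gives about 1 in 20, or 11.6. Each value below is the gap to the nearest other person as a share of the whole range. In control whole blood a person stood highest for TNF and NF-kB targets (0.663), and a person stood lowest for immature granule genes (0.686), eosinophil and basophil genes (0.685) and stem and progenitor genes (0.717). In patient CD14+ monocytes a person stood lowest for HLA class II genes, at a mean log2 CPM of 3.92 against 6.33 for the nearest (0.837). In control neutrophils a person stood highest for interferon-stimulated genes, at 7.91 against 5.39 (0.877), and for integrated stress response genes (0.849), and a person stood lowest for TNF and NF-kB targets (0.857). In patient neutrophils a person stood lowest for interferon-stimulated genes, at 6.31 against 8.23 (0.869), and a library had the lowest depth (0.915). In patient CD14-depleted cells a library stood highest for the haemoglobin share, at 2.04% against 0.606% (0.979), and for the share of the 50 most abundant genes, at 14.1% against 8.74% (0.929).

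In patients' whole blood, 24 of 24 immature granule and 16 of 17 erythroid genes rose and 15 of 18 B cell genes fell (adjusted p = 0.183, 0.117 and 0.154 for the lists with an estimated correlation). If the 2 libraries whose headers name the other group were mislabelled, the header groups should give at least as many changed genes. They gave 0. The count cannot settle which labels are right, since another split of the persons gave 5608. Without these 2 libraries 1044 genes changed, so the changes do not rest on them alone. Lower depth of some patient libraries is argued against, since 98.2% of the called members of these lists (54 of 55) stayed called with every person thinned to the same depth. A lower share of lymphocytes alone would raise immature and mature neutrophil genes alike. The immature list rose by 3.2 more on the log2 scale than the mature list, in 11 of 11 patients beyond every control (exact permutation test over 12376 rearrangements, two-sided p = 0.000727). A candidate explanation that stays open is that cells at earlier stages of granulocyte and red cell formation circulated in patients. It is a hypothesis from the same data, and treatment, which the labels do not give, was not tested. Of 20 glucocorticoid response genes, 14 were higher in whole blood and 11 in CD14+ monocytes at an unadjusted p under 0.05, and 0 were lower in either. In neutrophils 6 of 19 were higher and 1 lower, and in CD14-depleted cells 2 of 20 were higher and 1 lower. Over all genes and both directions, 4377 of 15427 had such a p in whole blood and 3820 of 14363 in CD14+ monocytes. The numbers were 4994 of 13762 in neutrophils and 2006 of 16204 in CD14-depleted cells.

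In patients' CD14-depleted cells, 0 of 24 immature granule genes passed over all genes in edgeR (24 at an unadjusted p under 0.05, 24 adjusted over the list alone, 21 in DESeq2), with a list median of 3.30 (camera adjusted p = 1.72e-37, adjusted p = 0.261 with an estimated correlation). Carry-over of cells of the neutrophil fraction is argued against: 24 of 24 of these genes had a higher mean in patients' CD14-depleted cells than in patients' neutrophils (20 to 24 genes in each of the 4 patients), with a median ratio of 18.7. Levels compared between fractions here are CPM of the joint fit of the fractions, which differ from those of the single fits. Mature neutrophil genes stood at a median of 4.26% of the neutrophil level, although 19 of 20 had a log2 fold change above 0 in CD14-depleted cells (median 1.11, camera adjusted p = 2.64e-05, adjusted p = 0.542 with an estimated correlation), so that some carry-over beside the immature genes stays open; MPO was at 824 against 14 CPM and FCGR3B, uncertain because of FCGR3A, at 208 (57.8 in controls) against 4350 CPM. A library that stands apart is argued against as the sole cause, since the list median was 2.64 at the lowest on leaving out 1 person, against 3.30 with all persons. Immature cells of low density that stay with mononuclear cells may be the source, a hypothesis that these data do not test further.

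In patients' neutrophils 1459 genes rose, 3 of 24 T cell genes fell and 0 of 59 ribosomal genes passed in edgeR (12 at an unadjusted p under 0.05, 2 in DESeq2), with list medians of -1.18 and -0.66 (adjusted p = 0.586 and 0.716 with an estimated correlation). In CPM of the joint fit of the fractions, T cell genes stood at 23.4% (SD 7.97, n = 4) of their level in CD14-depleted cells in controls and at 9.93% (SD 10.6, n = 4) in patients. The joint fit scales fractions otherwise than the single fits. UBA1 in control neutrophils averaged 195.4 CPM there, where the highest control in the neutrophil fit alone had 175.8. The percentages, and limits drawn from them, depend on that scale. A smaller carry-over of lymphocytes in patients could account for the lower ribosomal sum, itself not established gene by gene: it predicts a fall of 3374 CPM in their sum, 102% of the measured fall of 3311 CPM, from 9586 to 6275 CPM. For the higher genes it remains open in part: over all genes tested, 591 rose by more than 0.49 on the log2 scale, the largest rise that the T cell shares of single libraries allow (28 in the highest other split), among the 1459 that rose. With the T cell list mean as a covariate the 1459 genes had a median log2 fold change of 1.06 (median SE 0.32), against 1.40 (median SE 0.31) without it, and 328 of them still passed, as folds were smaller at about the same SE and the fit had fewer degrees of freedom. A difference of the neutrophils between patients and controls stays open too, as a hypothesis.

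The other splits of the persons tested the counts of changed genes as well. In whole blood, 2 of 100 splits, the real one included, gave as many genes as the real 1793. The other of these gave 5608, more than the real split, so the count of genes alone does not exclude chance. What sets the persons of that split apart was not tested. In CD14+ monocytes 1 of 35 splits, the real one, gave as many as 938, against 2 for the highest other, and in neutrophils 1 of 35 gave as many as 2144, against 39. This argues against chance in both without excluding it, as a share of 0.029 is the smallest that 35 splits can give. In CD14-depleted cells the real count was 0, so that 35 of 35 splits gave as many by construction (highest other 2), and the splits say nothing about chance there.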

How the results depend on the processing

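Leaving out the 2 libraries with another group in their headers, taking groups from headers, thinning, leaving out the shallowest library and the T cell covariate in neutrophils were chosen after seeing the data; the others were planned. Results not given here kept their count within 1.5 times under RLE scaling and without haemoglobin genes. DESeq2 moved the counts to 3227 (whole blood), 2271 (CD14+ monocytes), 3532 (neutrophils) and 750 (CD14-depleted cells), and the differences to 1584 (CD14+ monocytes against neutrophils), 163 (CD14+ monocytes against CD14-depleted cells) and 2086 (neutrophils against CD14-depleted cells); on simulated data it made more false calls. Without a filter, which tests more genes, the differences numbered 298, 9 and 484. A joint fit over 22 libraries gave 266 genes in CD14+ monocytes, 5360 in neutrophils and 389 in CD14-depleted cells. With the person as a replicate block, 20 genes differed between CD14+ monocytes and CD14-depleted cells and 1625 between neutrophils and CD14-depleted cells. In whole blood, a replicate block of label numbers, which name different persons and whose libraries did not pair (median r 0.09 over 6 pairs), gave 1162 genes. The T cell and erythroid list means as covariates gave 78, the 4 patients with fractions 1135, leaving out the 2 libraries 1044, and groups from the headers 0. The T cell list mean as a covariate left 422 genes in neutrophils. At a threshold of 0.01, CD14+ monocytes and neutrophils shared 14 genes. Except where said, the cause was not tested.

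Leaving out 1 person gave 1101 to 2509 genes in whole blood, 116 to 1282 in CD14+ monocytes, 531 to 5152 in neutrophils and 0 to 1 in CD14-depleted cells. The differences ranged from 59 to 3176, from 0 to 28 and from 108 to 4128 in the order above. The cause was not tested.

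With the T cell and erythroid list means as covariates, log2 fold changes in whole blood turned to -0.54 for IFI27, -0.10 for CDC34, -1.14 for UBB, -0.02 for PSMA4, -0.08 for DNAJA1, -0.60 for OPTN, -0.44 for GABARAPL2, -0.22 for GDF15, -0.15 for COX7C, -0.09 for NDUFA4, -0.30 for SLC2A1 and -0.03 for HK1. With groups from the headers they turned to -0.27 for IFI27 and -0.01 for PPBP. The cause was not tested. An estimated correlation ended the camera calls of all lists: 20 in whole blood, 22 in CD14+ monocytes, 13 in neutrophils and 16 in CD14-depleted cells. Fry called 6, 9, 12 and 0 of the 33 lists in the same order. In whole blood, thinning every person to the shallowest left 1379 genes. Depth limits what the shallow libraries show of weakly expressed genes: the shallowest had 8495 genes with 10 counts, where control libraries had at least 13655. That library, 1A, was summed with the deeper 1B of the same patient in the main tests. The shallowest person there was patient 9, with 5258886 counts and 12614 such genes.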

Other observations

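No test in this part was chosen after the result was seen. In whole blood, 5 of 19 platelet genes rose (6 adjusted over the list alone), with the adhesion receptor SELP at 1.86 ± 0.37 SE on the log2 scale and ITGA2B at 1.70 ± 0.43 (n = 6 controls and 11 patients; camera adjusted p = 0.000127, adjusted p = 0.5 with an estimated correlation). In neutrophils SELP rose by 2.90 ± 0.36 (n = 4 and 4) while PPBP, a platelet chemokine, stood at -2.72 ± 0.93 and did not pass (adjusted p = 0.073). In CD14+ monocytes the lipid carrier gene CLU rose by 4.37 ± 0.68, from 7.44 ± 7.15 CPM (SD, n = 3) to 154 ± 62.9 CPM (SD, n = 4), a call that leaving out some persons ended. HOXA9, a gene of stem and progenitor cells, rose there by 3.31 ± 0.57, from 0.354 ± 0.240 CPM to 3.51 ± 1.23 CPM, also with calls lost on leaving out some persons.

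In neutrophils, CD38 rose by 2.83 ± 0.37 and PRDM1 by 1.43 ± 0.21, both listed as plasma cell genes, and CD22, listed as a B cell gene, rose by 2.37 ± 0.41 from a low level of 0.946 ± 0.294 CPM. MYC fell by 2.05 ± 0.48 in neutrophils, a call that leaving out some persons ended, and NR4A1 fell by 2.78 ± 0.33 in whole blood. In whole blood, 7 of 26 glycolysis and hypoxia genes rose (11 adjusted over the list alone), with BNIP3L, a mitophagy receptor abundant in red cell precursors, at 2.59 ± 0.44 (camera adjusted p = 0.00051, adjusted p = 0.5 with an estimated correlation). PRG2, the eosinophil major basic protein, rose there by 4.50 ± 1.02, the lone riser among 15 eosinophil and basophil genes; 4 others fell adjusted over the list alone. Of 32 proteasome subunit genes, 3 rose in whole blood and 3 in neutrophils (camera adjusted p = 0.0187 in whole blood, adjusted p = 0.724 with an estimated correlation). Over all genes a similar share rose, 1327 of 15427 in whole blood and 1459 of 13762 in neutrophils. At an unadjusted p under 0.05, 7 members were higher and 0 lower in whole blood, and 6 higher and 4 lower in neutrophils. PSMA6 stood at 1.57 ± 0.36 in whole blood and 1.42 ± 0.28 in neutrophils, the latter a call lost on leaving out 1 person.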
